A study of Mus musculus with 27 samples.

How the data were processed

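The material came from a mouse model of B-cell lymphoma. VavP-Bcl2 mice carry a transgene that expresses the anti-apoptotic gene Bcl2 in blood cells. Haematopoietic stem cells from the livers of their embryos, taken at embryonic day 13.5, received an empty retroviral vector or MSCV-SHMT2, a retroviral vector that expresses SHMT2, and were transplanted into irradiated recipients, per the labels of the RNA-seq and ChIP-seq samples. The cells studied were B220-positive cells, from the spleen per the same labels, B220 being a surface form of CD45 that marks B cells. The labels of the ERRBS samples name B220-positive cells, the model and the vector, and do not describe the embryos, the transplant or the spleen. RNA-seq was made from 3 vector and 3 SHMT2 libraries, H3K4me1 ChIP-seq from 2 and 2, H3K4me3 ChIP-seq from 2 and 3, and enhanced reduced representation bisulfite sequencing (ERRBS), which reads methylation at CpG-rich parts of the genome, from 3 and 3. The 6 input libraries were not analysed here. Groups and replicate numbers were taken from the sample titles. For SHMT2 replicates 2 and 3 of the ERRBS set the transfection label reads SHMT3 and SHMT4, and the titles were followed. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. The peak names carry a code of unstated meaning that differs between the libraries of a mark, and sex markers differ between libraries of a group in RNA-seq and ERRBS.

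The deposited RNA-seq values were TPM, transcript abundances scaled to the same total in each library, for 23382 gene symbols, 1 table per library, made by the authors with STAR alignments to mm10 named in the submitters' processing notes. The tool that turned alignments into TPM is not given in the sources used here. TPM keep no sequencing depth, so the depth of these libraries is unknown. The RNA kit preserves strand per the labels, and whether the counting used strand is not given in the sources used here. The adult haemoglobin genes are listed at 0 in all 6 libraries, so a listed 0 was not read as absence. The deposited peak lists hold MACS2 peaks, broad for H3K4me1 and narrow for H3K4me3, called per library on BWA alignments to mm10 per the submitters' processing notes. Whether an input library served as control is not given in the sources used here. The fold enrichment and the −log10 q-value of each peak are the authors' values as deposited, and were used only to rank or filter peaks within a list. The ERRBS tables give, per the file headers, the coverage, a count of calls per cytosine, and the percent of calls read as C or T. Bismark, Bowtie2 and mm10 are named for them in the submitters' processing notes. The lowest coverage in these tables is 10 calls, both strands are listed apart, and sites are therefore called CpG cytosines. The protocol in the ERRBS labels describes bisulfite PCR of single fragments, so the steps between DNA and the deposited percent values are only partly known.

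Expression was tested on log2(TPM + 1), so fold changes are on that scale and understate the change of low genes. Genes with a mean of at least 1 TPM over the 6 libraries were kept, 11117 in all, and limma 3.58.1 in R 4.3.3 was fitted without a block (empirical Bayes with trend, Benjamini-Hochberg adjusted p under 0.05). In all, 28 gene lists were fixed, holding 674 members, of which 652 were found in the table, 17 of them under an older symbol. The 26 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with limma's fry. Counts adjusted over a list alone use the p-values of its members only. A list of 2 genes named by the study, Sash1 and Ptprm, was handled gene by gene. Single genes were also compared by a two-sided exact permutation test, whose smallest possible p is 0.1 for 3 against 3.

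Methylation was compared at autosomal CpG cytosines with coverage of at least 10 in all 6 libraries, 1211987 sites. The model was a binomial regression per site on methylated and total calls, with an overdispersion moderated across sites by a Python version of limma's variance squeezing and a two-sided F test. It ran on the 485096 sites whose mean level lay between 5 and 95 percent, on 64099 tiles of 1 kb and on 1243 promoters with at least 3 cytosines. A call needed an adjusted p under 0.05 and a difference of at least 25 percentage points for a site or 10 points for a tile or promoter. The bounds on the mean level were set after the data were seen. The gene annotation used here (GRCm38.p6, the build also called mm10) gives gene spans without strand. A promoter was therefore taken as the 1 kb on either side of the gene end that carried H3K4me3 in at least 1 of the 5 libraries, in place of an annotated transcription start site. Of 21887 protein-coding genes, 10947 had a single end marked, 1537 had both and 9403 had neither. Genes with both ends or neither marked were left out of the promoter tests, and an added test covered both ends of every gene.

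Peak regions were the merged union of the lists of a mark. A region was present in a library when a peak overlapped it by at least 1 bp, and specific to a group when present in every library of that group and in none of the other. Peak sets were compared by the Jaccard index of covered bases, with an exact permutation of the group labels over 3 splits for H3K4me1 and 10 for H3K4me3, which cannot go below 0.333 and 0.1. Changes in expression and promoter methylation were related across genes by rank and linear correlation with 100000 permutations of the genes, which are not independent replicates. Fisher's exact test of called promoters against called genes was planned and could not be made, since neither had calls.

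These choices, the gene lists and the rule for named genes were made before the data were examined, apart from the promoter definition, the bounds on the mean level and the alternatives said to be added. The rule named Shmt2, Sash1 and Ptprm, then the 10 higher and 10 lower genes with the smallest p among those with an absolute log2 fold change of at least 1 and no overlap between groups where too few passed the threshold, leaving out clone names. It also named the members with the smallest p in each list, 5 promoters and 3 tiles per direction, and up to 8 genes per direction with group-specific promoter H3K4me3. Some items that the rule named are not reported here. Alternatives were other pseudocounts, expression filters and scalings, a replicate block, other tests, leaving out each library, other coverage limits, pooled calls, other windows, stricter peaks, equal numbers of peaks and a larger overlap. The models were tested on simulated data made from the real libraries. With 50 genes changed per size, limma recovered 10% at a log2 change of 0.5, 60% at 1, 80% at 2 and 88% at 4. With 50 sites changed per size, the site model recovered 4% at 25 points, 50% at 40, 80% at 60 and 100% at 80, and the tile model 2% at 10 points, 14% at 25 and 66% at 40. The site simulation held 100000 sites, fewer than were tested. The overdispersion towards which tiles were moderated was 3.395 in the simulation and 4.124 in the data. Recovery in the data may therefore be lower, and none is given for promoters. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.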

Results

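B220-positive cells of the VavP-Bcl2 mouse model with empty vector or with SHMT2 were profiled by RNA-seq, ChIP-seq and ERRBS. SHMT2 is the mitochondrial serine hydroxymethyltransferase, which splits serine into glycine and a 1-carbon unit carried by folate, and 1-carbon units feed the methyl donor of DNA and histone methylation. The comparison asks whether raised SHMT2 goes with altered methylation of DNA and histone H3 and with lower expression of tumour suppressor genes. The RNA-seq depth is unknown. The ERRBS libraries held 1330340 to 1424115 cytosines at a mean coverage of 63.0 to 71.6 calls. The H3K4me1 lists held 33119 to 52056 peaks and the H3K4me3 lists 33313 to 38249 peaks.

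Shmt2 itself, on chromosome 10, was higher in the SHMT2 libraries, at 283 ± 54.7 TPM against 185 ± 34.4 TPM (mean ± SD, n = 3 each). Every SHMT2 library (244, 345 and 259 TPM) lay above every vector library (174, 223 and 157 TPM). The log2 fold change was 0.61 (SE 0.19), with an exact permutation p of 0.1, the smallest that 3 against 3 can give, and a limma adjusted p of 0.216. A mouse gene table need not count a transgene in full, so this value may miss part of the vector's transcripts.

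**Figure D1:**
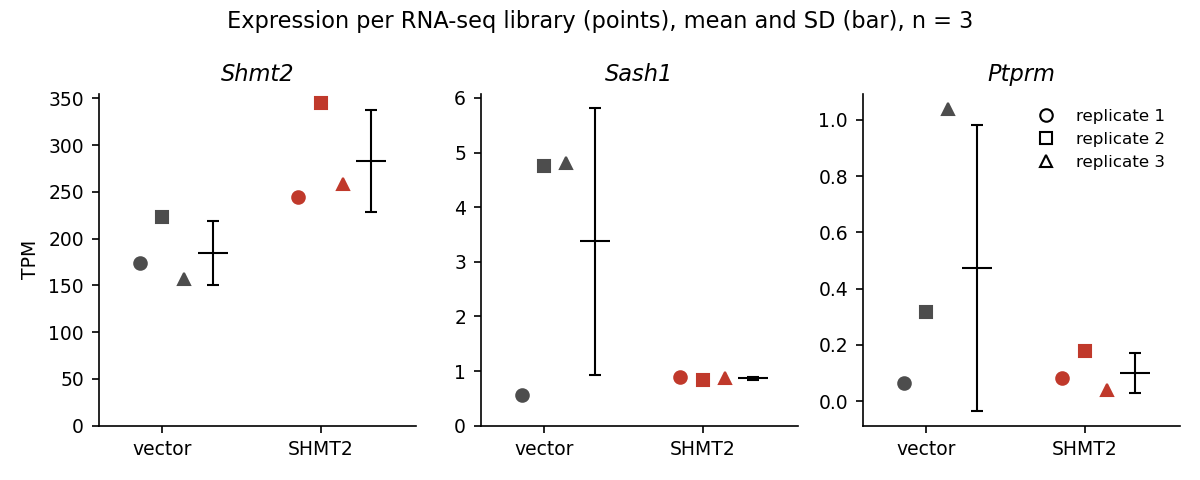
Expression of Shmt2, Sash1 and Ptprm in TPM on the y axes, with 1 point per RNA-seq library (grey vector, red SHMT2, shape by replicate) and a bar for the mean and SD of 3 libraries. Shmt2 is higher in all 3 SHMT2 libraries, and Sash1 is high only in vector replicates 2 and 3, at 4.76 and 4.82 TPM.

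Across the transcriptome no single gene passed the adjusted threshold. limma called 0 of 11117 genes at an adjusted p under 0.05, with 1858 genes at an unadjusted p under 0.05 where 556 would be expected by chance if genes were independent. Another split of the 6 libraries, with vector replicate 1 and SHMT2 replicates 2 and 3 on one side, gave 1565. In 2793 genes (25.1%) the groups did not overlap, against 10% by chance. Among genes with an absolute log2 fold change of at least 1 and no overlap, 15 were higher and 56 lower in SHMT2. The vector libraries were unlike one another: replicates 2 and 3 had high levels of erythroid and myeloid transcripts, described further on, with erythroid mean log2 levels of 7.67 and 5.43, against 2.70 in replicate 1 and 2.63 to 3.51 in the SHMT2 libraries. Without vector replicate 1, 850 genes passed (431 higher, 419 lower).

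The 10 higher and 10 lower genes named by the rule did not pass the threshold, with limma adjusted p from 0.204 to 0.245. The 10 higher genes included Csrp2, a LIM-domain protein (9.51 ± 5.64 TPM in vector, 22.3 ± 1.44 in SHMT2), the glutathione transferase Gstt1 (6.75 ± 3.97 and 18.7 ± 3.51) and the midbody protein Cep55 (5.10 ± 3.73 and 12.3 ± 0.663). The others were Zdhhc2, a protein palmitoyltransferase (log2 fold change 1.07), Smoc1 (1.03), Crisp3 (1.14), Klhl13 (1.87), Clec3b (1.25), Efhc2 (1.11) and D0H4S114 (1.37). The 10 lower genes included Tnfaip3, the NF-kB inhibitor A20 (781 ± 204 and 358 ± 63.9 TPM), Sesn1, a stress-induced inhibitor of mTORC1 (236 ± 110 and 75.9 ± 10.0), and the inhibitory receptor Ctla4 (64.7 ± 14.5 and 29.7 ± 3.92). The others were Mlxip, a glucose-sensing transcription factor (log2 fold change −1.14), Il20rb (−1.03), Trp53inp2 (−1.04), Sepp1 (−1.05), Plb1 (−1.95), Itgam (−1.19) and Ppfia4 (−1.54). Without vector replicate 1, Zdhhc2, Gstt1, Csrp2, Cep55, Ctla4, Il20rb, Sepp1, Tnfaip3, Ppfia4, Mlxip and Sesn1 passed, with limma adjusted p from 0.0161 to 0.0468. Of the vector libraries that fit keeps only replicates 2 and 3, which had high erythroid and myeloid transcripts. In some of these genes vector replicate 1 lay towards SHMT2, as in Sesn1 (110, 282 and 314 TPM in vector, 66.6 to 86.5 in SHMT2). In others it did not, as in Ppfia4 (19.6, 9.48 and 8.47 TPM in vector, 2.26 to 4.15 in SHMT2).

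Sash1 and Ptprm, the genes named by the study, did not pass either. Sash1, a scaffold protein studied as a tumour suppressor, stood at 0.558, 4.76 and 4.82 TPM in vector and at 0.899, 0.844 and 0.866 TPM in SHMT2. Its log2 fold change was −0.999 (SE 0.53), with an exact permutation p of 0.4 and a limma p of 0.384 adjusted and 0.106 unadjusted. Adjusting over the list alone left the unadjusted value as it was, since Ptprm had a mean under 1 TPM and was not tested by limma. The 2 vector libraries with high Sash1 were those with high erythroid and myeloid transcripts, and vector replicate 1 lay below all SHMT2 libraries. With the erythroid and myeloid marker level, high in the same 2 libraries, as a covariate the log2 fold change was −0.21 (SE 0.28, limma adjusted p = 0.755), and without vector replicate 1 it was −1.63 (limma adjusted p = 0.0161). Ptprm, a receptor-type tyrosine phosphatase, was barely detected, at 0.0634, 0.316 and 1.04 TPM in vector and 0.0834, 0.177 and 0.0394 TPM in SHMT2 (exact permutation p = 0.3). The study chose both genes on data that include these samples, so their direction is not independent evidence.

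The clearest group difference was in genes of mitochondrial respiration and translation, of which 35 of 36 measured members were higher in SHMT2 (median log2 fold change 0.35). The list rose by camera (adjusted p = 7.0e-12), as did its members by fry (adjusted p = 0.00796), but camera with an estimated correlation gave an adjusted p = 0.189. Adjusted over the list alone 23 members rose, while over all genes limma called 0 of them, with 24 at an unadjusted p under 0.05. Examples are Ndufs4, a complex I subunit (15.03 ± 0.127 TPM in vector, 23.8 ± 2.03 in SHMT2), the ATP synthase subunit Atp5o (75.1 ± 3.34 and 105 ± 5.75) and Ndufa2 (34.9 ± 1.75 and 47.9 ± 1.78). The list was called whichever library was left out, and with the erythroid and myeloid marker level as a covariate (mean log2 change 0.29, adjusted p = 2.2e-09).

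Myc targets, which serve ribosome assembly, protein folding and cell growth, rose by camera (27 of 34 higher, median 0.27, adjusted p = 1.2e-04), with an adjusted p = 0.901 with an estimated correlation. The mean change of 0.19 was 0.11 without vector replicate 3 (adjusted p = 0.0069). Adjusted over the list alone 7 members rose. They included the chaperonin subunits Cct5 (4496 ± 468 and 6841 ± 309 TPM) and Cct3 (138 ± 20.5 and 207 ± 15.8), and the DNA repair enzyme Apex1 (7.34 ± 1.55 and 11.8 ± 0.438). Genes of mature B cell identity rose slightly (26 of 32 higher, median 0.21, adjusted p = 0.0312, and 0.901 with an estimated correlation). None passed adjusted over the list alone, among them the Fc receptor-like gene Fcrla (241 ± 22.8 and 340 ± 43.6 TPM) and the costimulatory receptor Cd40 (29.3 ± 8.69 and 45.9 ± 4.74). The list was lower in vector replicates 2 and 3 than in the other 4 libraries (mean log2 difference −0.28, SE 0.06 over genes), and its call was lost without vector replicate 2 (adjusted p = 0.145), without vector replicate 3 (0.132) and with the marker covariate (0.602).

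Lymphoma tumour suppressors fell as a list by camera (24 of 35 lower, median −0.11, adjusted p = 0.0284, and 0.901 with an estimated correlation). Adjusted over the list alone, 0 members passed by limma, with 9 at an unadjusted p under 0.05, 7 of them lower. Those with the smallest p were Tnfaip3 (log2 fold change −1.11), the acetyltransferase Crebbp (143 ± 13.4 and 110 ± 6.50 TPM) and Sesn1 (−1.49). The call was lost without vector replicate 1 (median −0.12, mean −0.19, adjusted p = 0.0803) and without vector replicate 3 (mean −0.09, adjusted p = 0.0698), against a mean of −0.17 with all libraries. It held with the marker covariate (adjusted p = 0.00918) and without both vector replicates 2 and 3 (0.0162).

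Erythroid and myeloid genes fell as lists, through high levels in vector replicates 2 and 3. The erythroid list had a median log2 fold change of −2.20 (19 of 19 lower, adjusted p = 1.9e-05) and the myeloid list −1.10 (24 of 25 lower, adjusted p = 1.1e-04), each with an adjusted p = 0.901 with an estimated correlation. Spna1, the erythroid spectrin, stood at 6.82, 421 and 71.0 TPM in vector and 13.6, 5.13 and 12.6 TPM in SHMT2. Alas2, the haem synthesis enzyme of red cells, stood at 7.81, 297 and 79.9 and at 17.7, 6.24 and 24.997 TPM. Vcam1, abundant in splenic macrophages, stood at 27.2, 351 and 292 and at 35.6, 54.3 and 35.7 TPM, and Itgam at 12.6, 14.4 and 12.3 and at 8.06, 3.44 and 4.83 TPM. The other members with the smallest p were the myeloid Hmox1 (log2 fold change −1.35) and the erythroid Ermap (−2.51) and Rhag (−2.37). The erythroid mean of −2.07 was −3.35 without vector replicate 1 and −0.89 without vector replicate 2. The myeloid mean of −0.95 was −1.75, −0.50 and −0.61 without vector replicate 1, 2 or 3. Without both vector replicates 2 and 3 the erythroid mean was 0.57 (adjusted p = 0.103) and the myeloid mean 0.65 (adjusted p = 0.0135), the opposite direction.

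**Figure D2:**
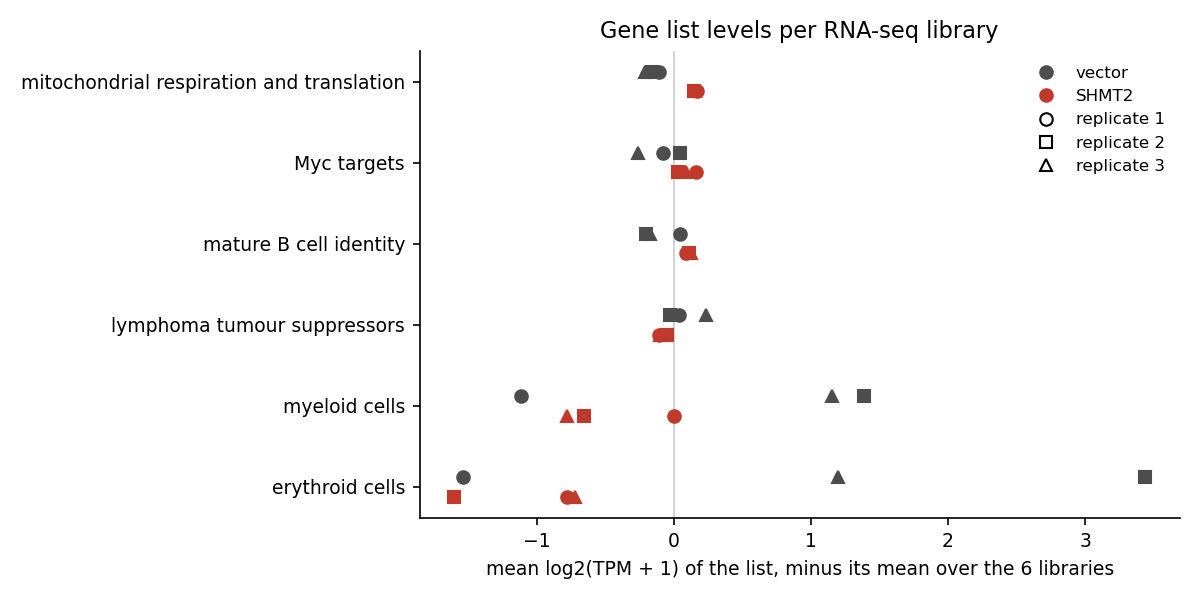
Mean log2(TPM + 1) of 6 gene lists in each RNA-seq library on the x axis, relative to the list's mean over the 6 libraries (grey vector, red SHMT2, shape by replicate). The mitochondrial list separates the groups, while the erythroid and myeloid lists are set by vector replicates 2 and 3.

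No other list passed camera. Serine and 1-carbon metabolism had a median log2 fold change of 0.18 (adjusted p = 0.205) and 1 member that rose adjusted over the list alone, Psph, the last enzyme of serine synthesis (10.98 ± 0.678 and 16.6 ± 0.672 TPM). Psat1, the enzyme before it, stood at 8.72 ± 2.80 and 15.3 ± 0.977 TPM. Of the DNA methylation machinery (median 0.01, adjusted p = 0.765), the 5-methylcytosine dioxygenase Tet3 fell (97.3 ± 11.6 and 66.5 ± 2.96 TPM) and Mbd3 rose (87.4 ± 6.48 and 117 ± 4.35) adjusted over the list alone. Of the H3K4 methylation writers and erasers (median −0.06, adjusted p = 0.373), Dpy30, a core subunit of the H3K4 methyltransferase complexes, rose adjusted over the list alone (16.7 ± 1.87 and 26.1 ± 1.82), and Men1, of the same complexes, stood at 29.3 ± 2.66 and 37.1 ± 2.18. Of the marginal zone and B-1 list (median −0.04, adjusted p = 0.517), Ctla4 and Itgam fell adjusted over the list alone. In each of these lists 0 members passed over all genes by limma, with 5, 5, 3 and 4 members at an unadjusted p under 0.05.

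In the remaining lists no member passed, even adjusted over the list alone. Germinal centre genes had a median of 0.47 (adjusted p = 0.127; Tnfrsf13c log2 fold change 0.34, Plxnb2 0.49), natural killer cells −0.47 (0.0857; Il2rb −0.49, Klrb1c −0.84), T cells −0.05 (0.733; Cd2 0.41, Cd3g 0.45) and dendritic cells −0.12 (0.733; Fscn1 0.60, Cd83 0.40). Plasma cells had −0.02 (0.733; 2010001M09Rik, an older symbol of Mzb1, 0.51 and Prdm1 −0.58), B cell progenitors −0.13 (0.690; Vpreb3 0.37, Smarca4 0.29) and stroma 0.03 (0.793; Madcam1 0.90, Stab2 −0.94). Proliferation genes had 0.15 (0.517; Gins2 0.62, Mcm5 0.51), p53 targets −0.10 (0.0793; Sesn1 −1.49, Btg2 −0.49) and NF-kB targets 0.00 (0.690; Tnfaip3 −1.11, Nfkb2 0.39). The interferon response had 0.08 (0.733; the immunoproteasome genes Psmb8 0.61 and Psmb9 0.72), B cell receptor signalling 0.15 (0.501; Ptpn6 0.34, Cd79a 0.34) and apoptosis regulators −0.02 (0.733; Bid 0.48, Bak1 0.60). The stress responses of the endoplasmic reticulum had 0.00 (0.942; the chaperones Canx 0.34 and Pdia6 0.57), polycomb and other repressors 0.04 (0.740; Ring1 0.34) and the RNA quality list 0.03 (0.765; Jund −0.60, Btg2 −0.49). Of the platelet list 3 genes were measured and no test was made (Itga2b −0.89, Clec1b −0.98). Median and camera differed in direction for the DNA methylation, stroma, NF-kB and RNA quality lists, as did the mean and camera for the stress responses of the endoplasmic reticulum. Natural killer genes were higher in vector replicates 2 and 3 than in the other 4 libraries (mean log2 difference 1.08, SE 0.15 over genes), and germinal centre genes had their lowest mean log2 levels there (5.90 and 6.83). The germinal centre list was called as higher without vector replicate 1 (adjusted p = 4.9e-04), without SHMT2 replicate 1 (0.0278) and with no filter on low values (0.0473), but as lower without both vector replicates 2 and 3 (median −0.29, adjusted p = 0.00643). The natural killer list was called as lower without vector replicate 1 (adjusted p = 0.00174) and without SHMT2 replicate 1 (0.00355). T cells were called without SHMT2 replicate 1 (0.00199), proliferation and 1-carbon metabolism without vector replicate 2 (4.6e-07 and 0.03003), and p53 targets, as lower, without vector replicate 2 (0.00246), without SHMT2 replicate 3 (0.0412), with the marker covariate (0.0149) and without both vector replicates 2 and 3 (0.0317). The H3K4 writers and erasers were called as lower in the last setting (0.0227).

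Mean DNA methylation of the whole library differed little between the groups, in a design too small to show that they are alike. The mean over 1211987 autosomal CpG cytosines was 31.5% ± 0.431 in vector and 31.9% ± 0.142 in SHMT2 (SD, n = 3 each), a difference of 0.424 percentage points (exact permutation p = 0.3, smallest possible 0.1). Weighted by calls, the level was 27.1%, 23.8% and 26.3% in vector and 25.4%, 27.95% and 27.3% in SHMT2, which was not tested. The regions kept their usual contrast: the gene end with H3K4me3 had a median methylation of 0.459% and the other end 90.4% over 1498 genes with both ends covered, and 96.5% of them were lower at the marked end.

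No single site or region passed the adjusted threshold. The moderated binomial model called 0 of 485096 CpG cytosines, with 24130 at an unadjusted p under 0.05 where 24255 would be expected, 0 of 64099 tiles (2221 unadjusted) and 0 of 1243 promoters (28 unadjusted). Fisher's exact test on pooled calls, which ignores the spread between replicates, called 6333 sites (4119 higher, 2214 lower), 5982 tiles (2788 higher, 3194 lower) and 109 promoters (88 higher, 21 lower). SHMT2 replicate 2 stood apart from the other 5 libraries, with 28191 cytosines at least 25 points above all of them and 13411 below, while no other library had more than 2665 in either direction. Unadjusted counts were 63769 sites, 8202 tiles and 126 promoters without SHMT2 replicate 3, 11288, 1005 and 15 without vector replicate 2, and 14195, 1334 and 15 without vector replicate 3, with 0 calls each time.

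**Figure D3:**
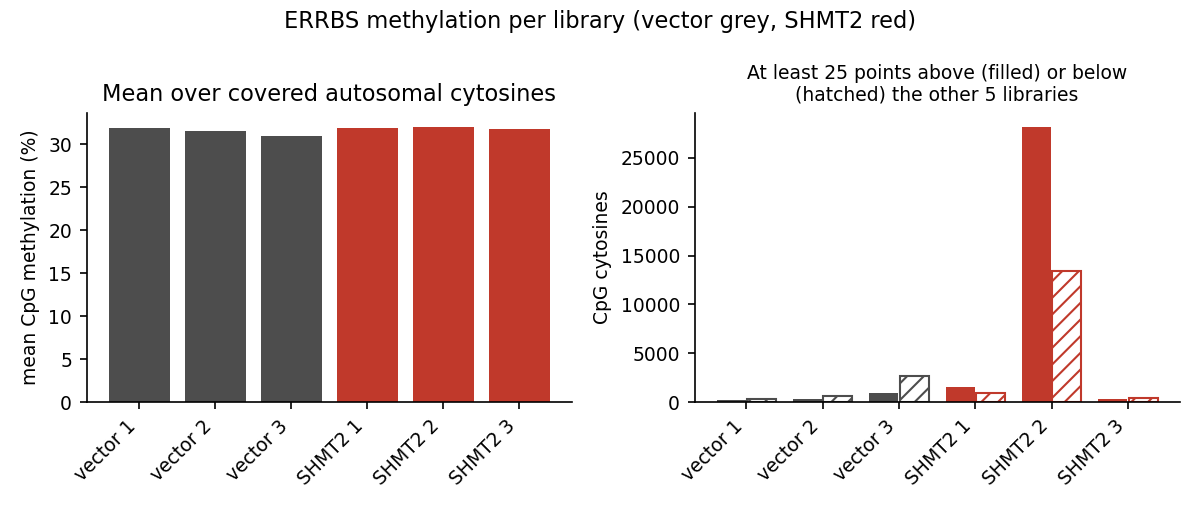
Mean CpG methylation in percent (left) and the number of CpG cytosines at least 25 percentage points above or below all other libraries (right) for each ERRBS library. The means lie between 31.02% and 32.04%, and SHMT2 replicate 2 holds 28191 cytosines above and 13411 below the others.

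The promoters named by the rule did not pass (adjusted p = 0.81). Higher in SHMT2 were the promoters of the actin-severing protein Scin at chromosome 12 position 40134228 (12.8% ± 4.36 in vector, 26.3% ± 1.78 in SHMT2, n = 3 each, at least 1593 calls per library), Lipo3 (21.1% and 44.5%), Mdfi (7.54% and 17.7%), Pla2g4e (12.3% and 31.5%) and Oxct2a (49.9% and 75.0%). Lower were those of the retinol dehydrogenase Rdh13 at chromosome 7 position 4471280 (24.1% ± 2.89 and 4.62% ± 1.67, at least 234 calls per library), Lemd2 (45.9% and 26.6%), Kcnj4 (53.3% and 38.8%), Inhbe (61.6% and 51.2%) and Akr1e1 (18.0% and 2.67%). Among tiles, the higher ones with the smallest p lay on chromosome 18 at 80236001 to 80237000 within Hsbp1l1 (difference 17.5 points, adjusted p = 0.636), chromosome 12 at 3235001 to 3236000, outside genes (30.6 points), and chromosome 11 at 95830001 to 95831000 at Phospho1 and Abi3 (39.8 points). The lower ones lay on chromosome 7 at 4470001 to 4471000 in Rdh13 and Eps8l1 (−19.4 points), chromosome 2 at 151888001 to 151889000 (−17.5 points) and chromosome 1 at 183547001 to 183548000 (−27.4 points), the last 2 outside genes. The groups did not overlap in these 6 tiles, which were chosen by their small p.

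At Sash1, 20 tiles had a mean methylation of 80.8% in vector and 80.1% in SHMT2, and at Ptprm 29 tiles had 77.3% and 77.8%. The Sash1 mean hides CpG-rich tiles of low methylation. That at 8885001 to 8886000 (47 cytosines) stood at 14.5%, 13.3% and 9.88% in vector and 26.7%, 61.15% and 9.31% in SHMT2. The next, at 8886001 to 8887000 (40 cytosines), stood at 9.93%, 9.51% and 9.32% and at 20.3%, 46.05% and 9.42%. SHMT2 replicate 2 was highest in each, and neither passed (model adjusted p = 0.889). A weak H3K4me3 region inside Sash1, from 8886019 to 8886579, lay in the tile at 8886001 to 8887000, away from both ends of the gene span. Promoters were sought only at gene ends, so this region was not tested as a promoter. Neither Sash1 nor Ptprm had H3K4me3 at an end, so they entered only the added test of both ends of every gene, which called 0 of 5984 ends (166 unadjusted). Of Sash1 only the end at position 8722217 was covered (14 cytosines, 90.8% in vector and 88.2% in SHMT2). The CpG-rich end of Ptprm at chromosome 17 position 67354491 (149 cytosines, at least 9726 calls per library) stood at 25.5%, 19.0% and 22.04% in vector and 31.95%, 65.7% and 18.9% in SHMT2, so its higher mean came from SHMT2 replicate 2. Of the tumour suppressors, Dapk1 (91 cytosines) showed the same pattern, at 32.1%, 19.0% and 21.2% and at 35.25%, 71.4% and 22.3%. The marked end of Prdm1, the plasma cell regulator Blimp-1 that is lost in some B-cell lymphomas, at chromosome 10 position 44528558 (8 cytosines, at least 591 calls per library), stood at 24.7%, 14.5% and 9.64% in vector and 32.7%, 27.7% and 37.7% in SHMT2, with no overlap. Its difference of 16.4 points did not pass (adjusted p = 0.81), and its RNA stood at 90.8 ± 8.03 and 61.4 ± 14.6 TPM (log2 fold change −0.58, limma adjusted p = 0.227). Of the ends of genes marked at both ends, that of the cell cycle inhibitor Cdkn2b at chromosome 4 position 89306289 (6 cytosines, at least 76 calls per library) stood at 6.58%, 4.0% and 2.61% in vector and 11.95%, 14.97% and 16.5% in SHMT2, also with no overlap, and entered only the added test. Dapk1, Prdm1 and Cdkn2b were chosen for naming after their values were seen.

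**Figure D4:**
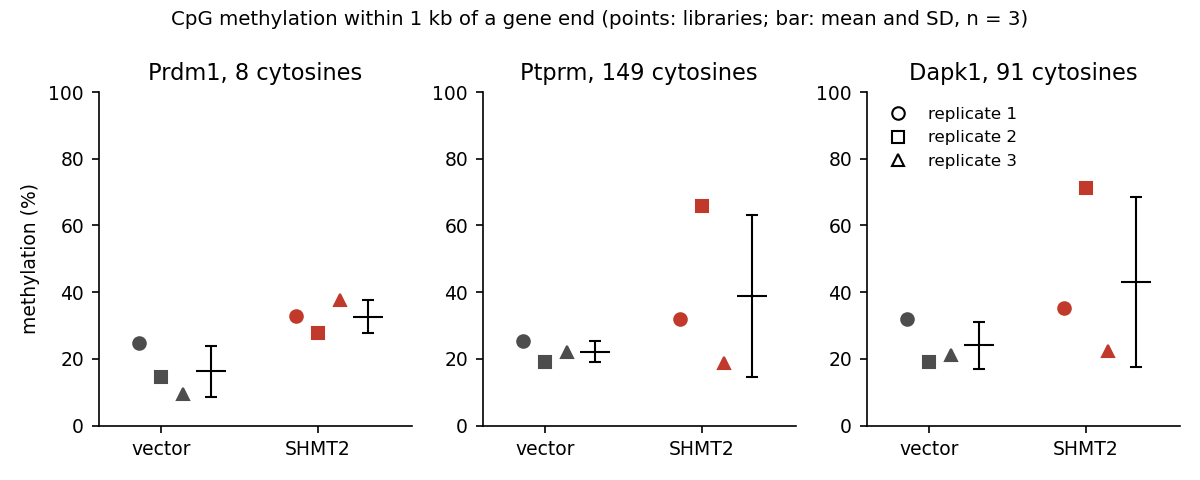
CpG methylation in percent within 1 kb of a gene end of Prdm1, Ptprm and Dapk1, with 1 point per ERRBS library (grey vector, red SHMT2, shape by replicate) and a bar for the mean and SD of 3 libraries. Prdm1 separates the groups, at 24.7% or less in vector and 27.7% or more in SHMT2, while Ptprm and Dapk1 are high in SHMT2 replicate 2 alone, at 65.7% and 71.4%.

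More of the genome was covered by H3K4me1, a mark of enhancers, in SHMT2 libraries. They held 48993 and 52056 peaks over 114 and 118 Mb, against 37274 and 33119 peaks over 77.5 and 62.6 Mb in vector. Of 55044 regions, 24738 were shared by all 4 libraries, 8858 were specific to SHMT2 and 14 to vector. SHMT2-specific regions were narrow (median 908 bp, against 2788 bp for shared ones) and weak, with a median at percentile 22.2 and 26.1 of the q-values within their lists. With the 15000 strongest peaks of each library the counts were 1157 and 650, and these peaks covered 65.2 and 64.85 Mb in SHMT2 against 49.55 and 41.2 Mb in vector. Leaving out SHMT2 replicate 4 or 5 or vector replicate 4 gave 16239, 13380 and 15819 SHMT2-specific regions, and vector-specific regions numbered 61 to 706 over the 4 libraries left out. Vector replicates 4 and 5 had a Jaccard index of 0.609, below the 0.633 of vector replicate 4 with SHMT2 replicate 4, while SHMT2 replicates 4 and 5 had 0.750. The mean index was 0.680 within and 0.560 between groups (exact permutation p = 0.333, the smallest possible). The difference of 0.120 was 0.251 without vector replicate 4, 0.0594 without SHMT2 replicate 4 and 0.0391 without SHMT2 replicate 5 (exact permutation p = 0.667). No H3K4me1 peak lay in the Y-linked Ddx3y, Kdm5d, Eif2s3y or Uty in either vector library, while SHMT2 replicate 4 had peaks in all 4 genes and SHMT2 replicate 5 in all but Eif2s3y. Xist had an H3K4me1 peak in vector replicate 4 alone, so the sex of vector replicate 5 is not shown. The list of vector replicate 5 was the weakest, with 1835 peaks at a −log10 q of at least 5, so a missing peak there says little. Sex and group cannot be told apart in this comparison.

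H3K4me3, a mark of active promoters, was shared by all libraries in 61.5% of regions, and most group-specific regions were of SHMT2. The peaks covered 34.05, 31.1 and 27.4 Mb in SHMT2 and 24.9 and 27.5 Mb in vector. Of 39361 regions, 24219 were shared by all 5 libraries, 808 were specific to SHMT2 and 64 to vector, and with the 15000 strongest peaks 141 and 62. Leaving out vector replicate 4 or 6 or SHMT2 replicate 5 or 6 gave 1410, 2136, 1273 and 2319 SHMT2-specific regions, and leaving out any but SHMT2 replicate 6 gave 122 to 522 vector-specific ones. The Jaccard index was 0.771 within and 0.752 between groups (exact permutation p = 0.2). A split with SHMT2 replicate 6 on the side of the vector libraries gave a larger difference, 0.0388 against 0.0187. It also gave more specific regions, 1514 against 872. Among 10947 promoters, 10049 (91.8%) carried the mark in all libraries, 47 only in SHMT2 and 2 only in vector, Elmo3 and D430019H16Rik. The SHMT2-specific promoters with the strongest peaks included those of Adam5, Lefty1, Eps8l1 and the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty. At Adam5 and Lefty1 both vector libraries had a peak 4 to 109 bp outside the window. No H3K4me3 peak lay in these 4 Y-linked genes in either vector library, while Xist had a peak in all 5 libraries. Y-linked H3K4me3 thus followed the groups, so sex and group are confounded here too. The Xist peaks covered 3689 and 3267 bp in vector and 1363, 545 and 3305 bp in SHMT2, so SHMT2 replicate 6 held both signals. No member of the fixed gene lists had group-specific promoter H3K4me3. In Sash1, H3K4me1 at chromosome 10 from 8925282 to 8926628 was present in both SHMT2 and neither vector library, and a weak H3K4me3 region from 8886019 to 8886579 was present in all but SHMT2 replicate 4. Ptprm had no peak of either mark, and Shmt2 had both marks in all libraries, with H3K4me3 from 127520083 to 127522674.

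**Figure D5:**
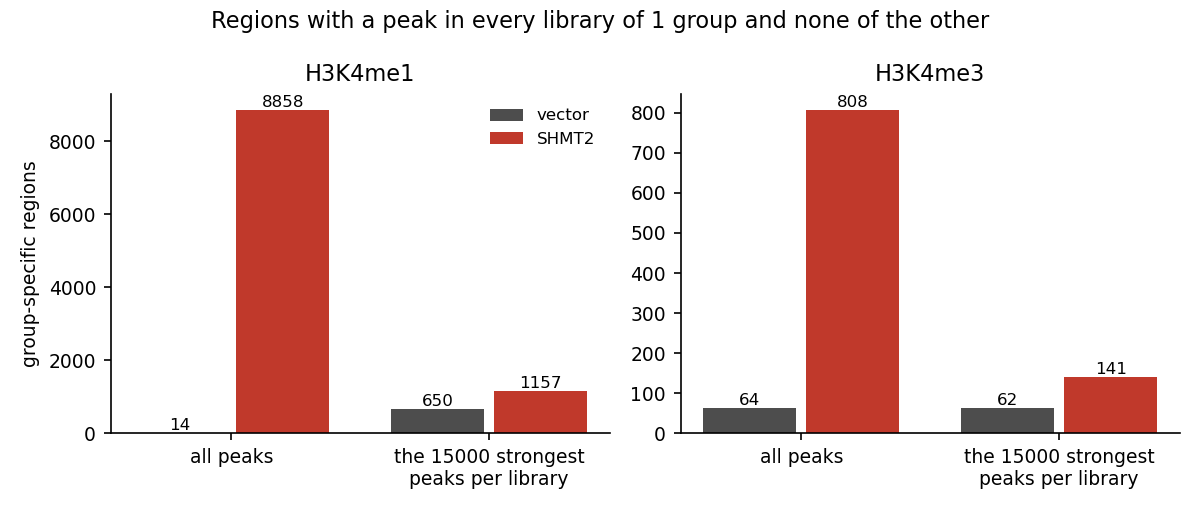
Number of regions with a peak in every library of 1 group and in none of the other, for H3K4me1 and H3K4me3, with all peaks and with the 15000 strongest peaks of each library (grey vector, red SHMT2). With equal numbers of peaks the H3K4me1 counts are 650 and 1157 in place of 14 and 8858.

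Expression and promoter methylation were only weakly related across genes. Over 7483 genes the rank correlation of the log2 fold change with the promoter methylation difference was −0.0568 and Pearson's r −0.0864 (permutation p = 1e-05 for each, the smallest that 100000 permutations give). The RNA-seq and ERRBS libraries are not matched by replicate number: RNA-seq SHMT2 replicate 2 had the Y-linked Ddx3y at 50.3 TPM and Xist at 2.17 TPM, while ERRBS SHMT2 replicate 2 had 186 cytosines on Y, against 1095 or more in 4 other libraries. Of these promoters 92.0% differed by less than 1 percentage point, which says little of stability, since the median methylation over the 9310 promoters with at least 3 cytosines was 0.339%. Of 30 promoters at least 10 points higher in SHMT2, 13 had higher expression (median log2 fold change −0.16), and of 12 at least 10 points lower, 8 did (median 0.24), against 4122 of all 7483 genes (median 0.03). The relation was lost without RNA-seq vector replicate 2 (−0.0086, permutation p = 0.456) and without ERRBS SHMT2 replicate 2 (−0.0137, permutation p = 0.236), and had the opposite sign without both RNA-seq vector replicates 2 and 3 (0.0699). Genes with SHMT2-specific promoter H3K4me3 had a median log2 fold change of 0.00 over 47 genes, against −0.34 over 2 genes with vector-specific H3K4me3 (permutation p = 0.263). The difference from genes marked in all libraries was −0.01 (permutation p = 0.641). Only 16 of the 47 reached a mean of 1 TPM, and their median level was 0.107 TPM, where changes on this scale lie near 0. Neither comparison could therefore show whether expression follows the mark.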

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

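The alternatives that leave out both vector replicates 2 and 3, that use the erythroid and myeloid marker level as a covariate, that drop the bounds on the mean methylation level, that take both gene ends, that leave libraries out of the correlation across genes, and that pair the mean methylation or the peak set similarity by replicate number were chosen after seeing the data. In all, 580 alternatives were run for 42 results, and 511 kept the direction and side of the threshold, or the count within 1.5 times. For the named genes 298 of 310 did so, and the other 12 were genes that passed only without vector replicate 1. Shmt2 expression and the relation of expression to promoter H3K4me3 kept theirs under all alternatives run. So did the direction of the mean methylation difference and of the H3K4me1 similarity difference (0.120, and 0.0391 without SHMT2 replicate 5 to 0.251 without vector replicate 4), in designs too small for a test to pass.

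RNA genes past the threshold ranged from 0 to 850 when a library was left out, and numbered 1 (Pde1b) with the marker covariate and 6 without both vector replicates 2 and 3, where the lone vector library is assumed to vary like the others. Called lists numbered 0 with an estimated correlation and 1 with fry, the mitochondrial list. With an estimated correlation the unchanged mean log2 changes (mitochondrial 0.32, Myc 0.19, mature B cell 0.22, tumour suppressors −0.17, myeloid −0.95, erythroid −2.07) no longer passed, and with fry only the mitochondrial one did. The mature B cell mean also failed at a mean of at least 5 TPM (0.22), with quantile normalization (0.22), with the marker covariate (0.12) and without both vector replicates 2 and 3 (0.0668), and ranged from 0.17 to 0.29 with a library left out. The tumour suppressor mean failed with no filter (−0.17) and ranged from −0.2253 to −0.0931 with a library left out. The erythroid mean was −0.12 with the marker covariate, which is built from it, and 0.57 without both vector replicates 2 and 3. The myeloid mean turned to 0.12 and 0.65 in the same settings. With a library left out the Myc mean ranged from 0.11 to 0.26, the erythroid from −3.35 to −0.89 and the myeloid from −1.75 to −0.50.

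Fisher's exact test on pooled calls gave 6333 sites, 5982 tiles and 109 promoters in place of 0, since it ignores the spread between replicates. SHMT2-specific H3K4me1 regions numbered 1157 with the 15000 strongest peaks and 13777 with an overlap of 50%, and 10835 to 16239 with a library left out. Vector-specific ones numbered 0 with a −log10 q of at least 5, 650 with the 15000 strongest peaks, 29 with an overlap of 50%, and 61 to 706. A −log10 q of at least 5 was reached by 6715 and 1835 H3K4me1 peaks in vector and 21446 and 17683 in SHMT2. For H3K4me3 the SHMT2-specific count was 141 with the 15000 strongest peaks and 1073 to 2319 with a library left out, and the vector-specific count 85 to 522. Fewer libraries ease the rule for a specific region, and the cause of the other shifts was not tested. The H3K4me3 similarity difference ranged from −0.0016 (without vector replicate 4) to 0.0437. The correlation of expression and promoter methylation ranged from −0.0828 to −0.0086 with a library left out, and was 0.0699 without both RNA-seq vector replicates 2 and 3. The cause was not tested.

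Replicate numbers did not pair the samples. After the group mean of each gene or site was taken out, the deviations of same-numbered libraries had correlations of −0.417, −0.332 and −0.0578 in RNA. In ERRBS they were −0.0482, −0.229 and −0.0639. With the replicate block limma called 0 genes (1180 unadjusted), 6 lists and no change for Shmt2 (0.61), and the methylation model 0 sites, 0 tiles and 0 promoters. Paired by number, the mean methylation difference of 0.424 points had an exact permutation p of 0.5 (smallest possible 0.25), and the similarity differences, 0.120 for H3K4me1 and 0.0187 for H3K4me3, had exact permutation p of 0.5 and 0.25, the smallest possible. The peak region counts come from no test, so they have no paired value. Rescaling without immunoglobulin and mitochondrial genes was not run, since the table lists none, nor was coverage of at least 5, since the tables start at 10. The RNA-seq depth is unknown, so the smallest detectable change cannot be set from it.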

Other observations

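All tests in this part were chosen only after the results were seen, apart from the gene lists they use and the other splits of the samples. Whole families of housekeeping complexes, which share members with the fixed lists, were higher in SHMT2. All 74 measured mitochondrial ribosome genes (Mrpl and Mrps) were higher (median log2 fold change 0.28, camera adjusted p = 4.4e-15 and adjusted p = 0.0487 with an estimated correlation). So were 33 of 35 complex I genes of the Nduf family (median 0.37) and 14 of 14 ATP synthase genes (0.38), each with an adjusted p = 0.0487 with an estimated correlation. The proteasome (median 0.34, 36 of 38 higher), the cytosolic ribosome (0.29, 63 of 74), the chaperonin (0.44, 7 of 7) and Snrp spliceosome genes (0.38, 10 of 11) were higher too, with adjusted p of 0.129, 0.325, 0.168 and 0.202 with an estimated correlation. Mitochondrial carriers of the Slc25 family (−0.01), zinc finger genes (−0.03, lower by camera with an adjusted p = 0.00983 and an adjusted p = 0.635 with an estimated correlation) and Vps sorting genes (0.01) had medians near 0, whose sign turned with quantile normalization for Slc25 (0.06) and zinc finger genes (0.00) and with median-ratio scaling for Vps genes (−0.02). The higher families were higher under both scalings as well. The mitochondrial list holds 5 of the mitochondrial ribosome, 13 of the Nduf and 3 of the ATP synthase genes, and the Myc list 3 of the chaperonin genes. Without members of any fixed list the medians of these 4 families were 0.28, 0.37, 0.38 and 0.43, but the first 3 no longer passed with an estimated correlation (adjusted p = 0.0544 each).

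Vector replicate 1 had transcripts of its own. Dip2b stood at 911 TPM there and at 247 and 254 in the other vector and 232 to 237 in the SHMT2 libraries, and the receptor gene Amhr2 at 22.6 TPM against 0.700 or less elsewhere. F8, the coagulation factor VIII gene, stood at 188 TPM against 72.1 or less, and Ftsj2 at 51.3 against 8.19 or less. These genes were 4 of the 6 that passed without both vector replicates 2 and 3. Numbers of marked list promoters were close between H3K4me3 libraries: 6 of 28 myeloid genes were marked in each, and 9 or 10 of 22 erythroid genes. Of 21 T cell genes, 11 and 11 were marked in vector and 9, 9 and 8 in SHMT2. The erythroid list shares Tfrc with the Myc targets, and the myeloid list shares Itgam with the B-1 list and Cebpb with the stress response list.

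The first pattern weighed is that Sash1 and the erythroid and myeloid lists are higher in vector replicates 2 and 3. A lower share of B cells alone, which would raise all other cell types alike, is argued against, since the T cell list was 0.31 (SE 0.10) higher there on the log2 scale and the erythroid list 3.48 (SE 0.18). Whether RNA of erythroid and myeloid cells accounts for Sash1 stays open: Sash1 and the markers are high in the same 2 libraries, so its change of −0.21 (SE 0.28) with the marker covariate, against −0.999 without, follows from the pattern itself. B220 selection is meant to remove such cells, and Lyz2 (79.4, 128 and 125 TPM in vector, 171, 120 and 128 in SHMT2) did not set vector replicates 2 and 3 apart. Of the myeloid list, however, 25 of 25 genes were higher there than in the other libraries on average (mean log2 difference 1.91, SE 0.17 over genes). Spna1 reached 421 TPM in vector replicate 2, and the haemoglobin genes, listed at 0 in all 6 libraries, do not bear on the question. An effect of SHMT2 on Sash1 stays open, since only vector replicate 1 has markers near the SHMT2 level: the SHMT2 libraries lay 0.26 above it.

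The second pattern is that the mitochondrial respiration and translation list is higher in SHMT2. Gene span and expression level as the whole cause are argued against, since the highest median of 10000 random lists matched on both was 0.28, below 0.35. The middle value of these lists was 0.09. Random lists hold unrelated genes, so their spread may be too narrow a yardstick for genes that move together. RNA of erythroid and myeloid cells as the whole cause is argued against by a mean change of 0.29 with the marker covariate (0.32 without). A general rise of housekeeping complexes may account for part of it, since the lowest family median among cytosolic ribosome, proteasome, chaperonin and spliceosome was 0.29. Against the single vector library left without both vector replicates 2 and 3, these medians were 0.31, 0.24, 0.35 and 0.14 and that of the mitochondrial ribosome 0.23, and whether SHMT2 lies behind the rise was not tested.

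The third pattern is that more H3K4me1 regions were specific to SHMT2 than to vector. Whether depth or sensitivity of peak calling accounts for the excess in counts stays open. With equal numbers of peaks the ratio of specific regions was 1.78, against 633 with all peaks. This ratio cannot tell depth from a gain of the mark, since equal numbers draw the counts together in either case. The wider coverage remained with equal numbers, at 65.2 and 64.85 Mb in SHMT2 against 49.55 and 41.2 Mb in vector. Equal numbers did not make the peaks equally strong: the −log10 q at rank 15000 was 6.36 and 5.49 in SHMT2 and 3.66 and 2.88 in vector. The coverage thus does not settle the question of sensitivity either. An effect of SHMT2 on H3K4me1 stays open, since 2 against 2 libraries make 3 splits and the exact permutation p of 0.333 is the smallest possible. Sex also stays open, since Y-linked H3K4me1 followed the groups.

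The 10 splits of 6 libraries are too few for a share under 0.05. In the 10 of 10 splits, RNA genes past the threshold numbered 0 in the real split and at most 0 in the others (1858 and at most 1565 unadjusted by limma). Called gene lists numbered 6 in the real split and 6 to 14 in the others, so no split had fewer than the real one. The 14 were reached where vector replicates 1 and 3 stood with SHMT2 replicate 2 or 3, so the samples have a structure apart from SHMT2. The mean change of the mitochondrial list was 0.32 in the real split, the largest in 1 of 10, with 0.147 as the highest other. Camera also called this list in 6 of the 9 other splits (adjusted p down to 7.1e-05), so a small camera p alone does not set the real split apart. The methylation model called 0 sites, tiles and promoters in the real split and at most 0 in the others, with 24130 sites unadjusted in the real split and up to 49961 in another. For the correlation of expression and promoter methylation, 41 of 100 pairs of an RNA-seq and an ERRBS split gave a value as far from 0 as −0.0568, the highest other being 0.136, so chance is not excluded.

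Levels of sex-linked transcripts did not follow the groups in RNA: Xist stood at 2461, 412 and 1635 TPM in vector and 30.5, 2.17 and 1625 TPM in SHMT2, and the Y-linked Ddx3y at 0, 69.2 and 17.2 and at 75.4, 50.3 and 7.96 TPM. Vector replicates 2 and 3 and SHMT2 replicate 3 held high Xist together with Ddx3y, so these libraries cannot be given a single sex. In both histone marks Y-linked genes did follow the groups, for H3K4me3 with Ddx3y, Kdm5d, Eif2s3y and Uty marked in all 3 SHMT2 and neither vector library, and for H3K4me1 with peaks in 4 and 3 of these genes in the SHMT2 libraries and none in vector. Sex and group cannot be told apart there, though vector replicate 5 had no H3K4me1 peak in Xist either, so its sex is not shown. In ERRBS, vector replicate 1 and SHMT2 replicate 2 had 185 and 186 cytosines on Y, against 1095 to 1158 in the others. In ERRBS SHMT2 replicate 2, 318 of 16202 gene ends were at least 25 points above all other libraries and 30 below. Of its higher cytosines 58.1% averaged under 20% elsewhere, but the same share was 58.1% in SHMT2 replicate 1 and 18.4% to 49.1% in the others. The correlations of SHMT2 replicate 2 with the other libraries were 0.938 to 0.953. Its Kit and Mme ends stood at 53.2% and 55.2%, against 19.05% and 33.2% or less elsewhere. The lower methylation of the Rdh13 end and the SHMT2-specific H3K4me3 at the start of Eps8l1 lie in overlapping genes on chromosome 7, at positions 4471280 and 4460638. The 4390 tiles in SHMT2-specific H3K4me1 regions had a mean methylation of 23.1% in vector and 24.0% in SHMT2 (exact permutation p = 0.2).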
